A study of Homo sapiens with 6 samples.

How the data were processed

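The series holds RNA-seq libraries of 8505C thyroid carcinoma cells, 3 labelled with a control hairpin and 3 with a hairpin against HHEX. Per the labels' protocols, RNA was isolated with Trizol, captured with an mRNA capture kit and made into libraries with a TIANSeq kit. Whether the kit keeps strand is not stated, and the aligner, the counter and the genome build are not given in the sources used here. The authors deposited a table of raw counts per gene, which are whole numbers with a different total in each library. The table also holds 6 columns of values per sample in another unit, which were not used. Start and end coordinates of 58672 of the 58735 named genes equal those of the GENCODE annotation of GRCh38 used here, and the coordinates given are those of the table. The column names give the group of a library but not its replicate label, so columns were mapped to groups only.

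A further 998 of the 59733 rows hold assembled loci without a gene name. They took 0.239% to 0.298% of the counts of a library and stayed out of library sizes and tests. Total counts over named genes were 15067566 in KD1, 14052770 in KD2, 14552665 in KD3, 13333245 in control1, 15144176 in control2 and 14673875 in control3. Mitochondrial genes took 3.61% to 4.33% of the counts and the 10 most abundant genes 6.01% to 8.95%. At these totals a floor of 3 counts lies at 0.196 to 0.225 CPM. Reads carry no molecular identifiers, so that Poisson intervals cover counting error only.

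Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 14280, libraries were scaled by TMM, and glmQLFit with robust estimation and glmQLFTest compared the 2 groups without covariates. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. CPM were computed with TMM factors, and log2 CPM with a prior count of 2. Differences from the control mean were taken on this log2 scale, and for a control library from the mean of the other 2. Library similarity was described by Pearson correlation, principal components and, for pairs of libraries, a chi-square per gene over genes with at least 20 counts in the pair.

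Lists of genes were written before the data were examined, and 753 of 755 list entries were matched to the table by current or older symbols. The 36 lists covered thyroid differentiation, Wnt targets, TLE co-repressors, epithelial and mesenchymal genes, DNA replication, mitosis, nucleolar MYC targets, MAPK output, immediate early genes, TGF-beta targets, YAP and TAZ targets, Notch targets, angiogenic factors, hypoxia and glycolysis, p53 targets, apoptosis, interferon response, NF-kB cytokines, the ATF4 amino acid response, the unfolded protein response, heat shock, cholesterol synthesis, fatty acid synthesis, NRF2 targets, nuclear oxidative phosphorylation genes, mitochondrial DNA genes, ribosomal proteins, replication-dependent histones, collagen and matrix, integrins, nuclear transcripts that mark RNA quality, and markers of fibroblasts, leukocytes, endothelium and neural cells. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the lists. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the genes, which lowers its power.

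The rule for named genes was also set before the data were examined. It took HHEX, the 12 highest and 12 lowest log2 fold changes among changed genes whose groups do not overlap and whose mean is at least 5 CPM in the higher group, up to 4 tested members of each list with the smallest p, the TLE genes, and the 5 most abundant changed genes in each direction. Genes named outside the rule are HSPA1A, HSPA1B, HSPB1, TRIM22, KITLG and TIPARP, and, in the closing section, genes picked for each library labelled HHEX shRNA among the 12 farthest above and the 12 farthest below the control mean at 20 CPM or more. Some genes that the rule or the lists take are not reported here by name.

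The fit was tested on simulated counts drawn from the means and library sizes of the 14280 genes, with 100 genes changed 2-fold and 100 changed 4-fold. With the dispersion fitted over all 6 libraries, 41% of the 2-fold and 87% of the 4-fold genes were recovered with 14 false calls among 14080 unchanged genes. With the dispersion of the 3 control libraries alone, 73% and 95% were recovered with 12 false calls. In the simulated list test the shifted list was called, as were 0 of the unshifted lists. Simulated genes were drawn independently of each other, whereas the estimated correlation reached 0.882 in the DNA replication list. The simulation thus does not show how the list test fares with correlated genes.

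Alternatives planned beforehand were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, limma-voom, other filters on low counts, glmTreat against a fold of 1.5, an estimated correlation, fry, and leaving out each library. Inclusion of the unnamed loci, voom with library quality weights, and a loess correction for GC content and transcript length were added after the data were seen. Figures were drawn with matplotlib.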

Results

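RNA was sequenced from 8505C cells, an established line of human anaplastic thyroid carcinoma, after short hairpin RNA against HHEX or a control hairpin. HHEX encodes a homeobox transcription factor that acts in thyroid development and can repress its targets together with TLE co-repressors. Each group held 3 libraries, named control1 to control3 and KD1 to KD3 in the deposited count table. The labels call them biological replicates. Their titles give 2 libraries of each group the same first number, and the sources used here do not say which columns those are. The titles of the control samples name a control hairpin while their genotype label reads wild type. Total counts over named genes ranged from 13333245 in control1 to 15144176 in control2, and 14280 genes were tested.

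HHEX itself (ENSG00000152804, chromosome 10, 92689951 to 92695646, plus strand) was measured first, since it shows whether the labels hold. It lay at 12.5 ± 0.439 CPM (SD, n = 3), the count scaled to library size, in the control libraries. In the library labelled KD2 it was 7.94 CPM (exact 95% Poisson interval 6.53 to 9.56) and in the library labelled KD3 7.13 CPM (5.81 to 8.66), which are 63.6% and 57.1% of the control mean. In the library labelled KD1 it was 14.8 CPM (12.9 to 16.9), or 118% of the control mean, so the target goes against that label. These intervals cover counting error only. The group difference was a log2 fold change of −0.33 (SE 0.28, 95% confidence interval −0.96 to 0.31), which did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.527). The exact two-sided permutation p was 0.4, where 3 against 3 libraries cannot go below 0.1. Every direction given hereafter for the libraries labelled HHEX shRNA includes KD1, and KD1, KD2 and KD3 stand for the libraries that carry these labels.

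**Figure D1:**
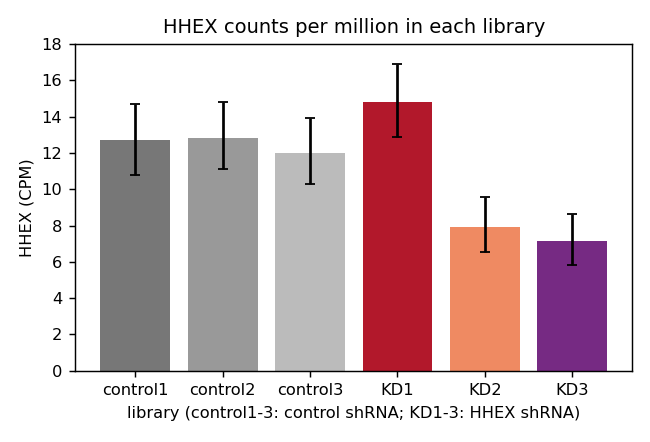
HHEX in CPM (vertical axis) in each of the 6 libraries (horizontal axis), with exact 95% Poisson intervals as error bars. The libraries labelled KD2 and KD3 lie at 7.94 and 7.13 CPM, below the controls at 12 to 12.8 CPM, and the library labelled KD1 lies at 14.8 CPM.

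The comparison of the 2 groups shows which transcripts differ by label. Since HHEX itself did not pass the test between them, the comparison cannot tell which transcripts depend on HHEX. By camera with a preset correlation, chaperone genes of the heat shock response were higher in the libraries labelled HHEX shRNA, and genes of the interferon response, histones and the unfolded protein response were lower. None of these 4 lists passed with an estimated correlation (adjusted p = 0.0594, 0.428, 0.0594 and 0.48), and each held at least 1 gene that passed edgeR's test. MMP3, a matrix-degrading protease, rose from 6.39 ± 1.71 to 28.9 ± 8.88 CPM (SD, n = 3 per group), a log2 fold change of 2.18 (SE 0.28, edgeR adjusted p = 0.0334). INHBA, a subunit of activin A, rose by 2.09 on the log2 scale (SE 0.22, edgeR adjusted p = 0.0173), and SERPINB2, an inhibitor of plasminogen activators, by 1.99 (SE 0.22, edgeR adjusted p = 0.0188). CXCL8, a chemokine of neutrophils, rose by 1.46, PGF, a placental growth factor, by 1.44, and KITLG, the ligand of the KIT receptor, by 0.96. RGS2, a regulator of G protein signalling, rose by 1.61, and SGK1, a kinase induced by serum and glucocorticoids, by 1.43. PLCXD2 and TIPARP rose by 1.11 and 0.86. On the lower side, PSG5, a pregnancy-specific glycoprotein, fell by 2.29 on the log2 scale, from 6.29 ± 0.0867 to 1.28 ± 0.121 CPM. KRT17, a keratin of basal epithelium, fell by 1.77, from 33 ± 5.37 to 9.68 ± 0.752 CPM. SREBF1, a transcription factor of lipid synthesis, fell by 0.95.

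In all, 26 genes changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 15 higher and 11 lower. Each of the 26 had every library of one group above every library of the other, as did 3560 of the tested genes, or 24.9%. Chance gives 10% only where all 6 libraries vary independently. KD1 and KD2 correlated at r = 0.989, against 0.955 and 0.956 with KD3, and may not be independent. The excess over 10% is thus no measure of a group effect. TRIM22, an antiviral protein, had the lowest log2 fold change (−3.78, SE 0.54, edgeR adjusted p = 0.045), at 3.96 ± 0.945 CPM in the controls and 0.279 ± 0.211 CPM in the libraries labelled HHEX shRNA. It lies under the expression minimum for named genes and was named, as were KITLG and TIPARP, after its values were seen. TRIM22 shares part of its annotated span with TRIM5, PLCXD2 with PHLDB2, SREBF1 with RAI1, RSAD2 with CMPK2, PDIA5 with SEC22A, and MMP3 with WTAPP1, and the counting is not stated to use strand, so reads of these pairs are uncertain. The same holds for PSG5 and the histone genes, which have near-identical relatives. The count of changed genes rested on the set of libraries. Without KD1, KD2, control2 or control3 edgeR called 0 genes (1789, 1625, 1947 and 1806 genes at an unadjusted p under 0.05), without control1 only ISG15, and without KD3 4675 genes, while DESeq2 called 774 genes over all 6 libraries.

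**Figure D2:**
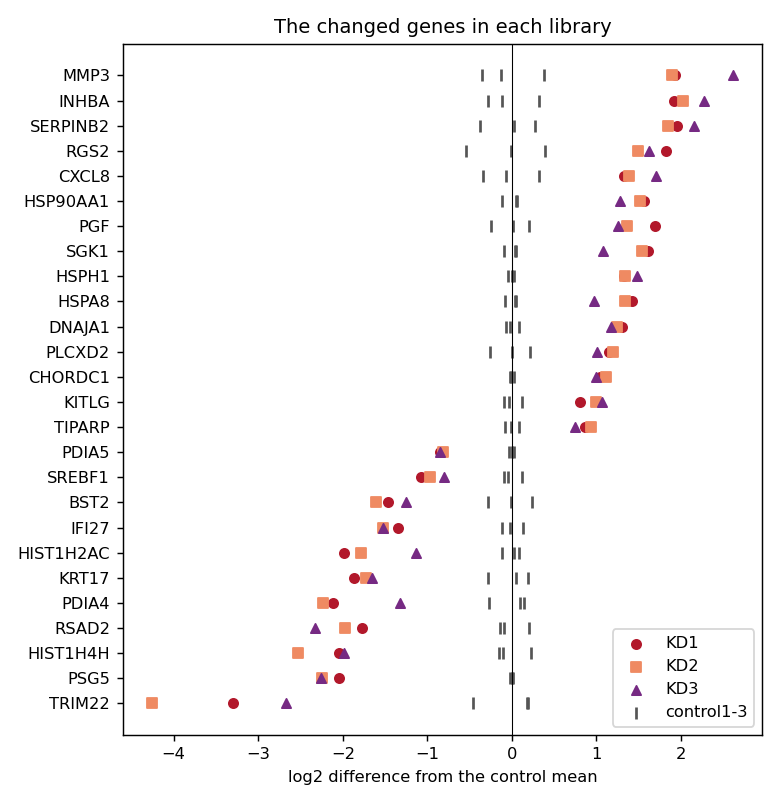
The 26 changed genes (vertical axis) with the log2 difference of each library from the control mean (horizontal axis). Circles, squares and triangles are the libraries labelled KD1, KD2 and KD3, on the log2 CPM scale with its prior count. Grey ticks are the 3 control libraries, as the log2 ratio of CPM to the mean CPM of the controls without a prior count. All 15 higher genes lie to the right of every control library and all 11 lower genes to the left, from −3.78 (TRIM22) to 2.18 (MMP3) as fitted log2 fold changes.

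Chaperone genes of the heat shock response were higher in each library labelled HHEX shRNA. Of 14 tested members, 5 rose over all genes tested and 13 when adjusted over the list alone. HSP90AA1 rose from 1610 ± 102 to 4420 ± 444 CPM (log2 fold change 1.46, SE 0.18), HSPH1 from 214 ± 4.98 to 558 ± 33.5 CPM (1.39, SE 0.13), and DNAJA1 from 177 ± 9.7 to 417 ± 18.6 CPM (1.24, SE 0.12). The others were HSPA8, at 1.26, and CHORDC1, at 1.05. The list median was 1.03 in the library labelled KD1, 0.99 in KD2 and 1.08 in KD3, as log2 difference from the control mean. HSPA1B, which has a near-identical copy in HSPA1A and shares reads with it, stood at 31.9 CPM in the controls and at 99.9, 109 and 699 CPM in KD1, KD2 and KD3. It did not pass the test (edgeR adjusted p = 0.12). HSPB1 had the only negative log2 fold change of the list, −0.55 (edgeR adjusted p = 0.386). By limma's camera with a preset correlation the list was higher (adjusted p = 1.24e-10), with an adjusted p = 0.0594 with an estimated correlation.

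Replication-dependent histone genes were lower in each library labelled HHEX shRNA. All 9 tested members of the list had a negative log2 fold change, 2 fell over all genes tested and 7 when adjusted over the list alone. HIST1H4H fell by 2.28 on the log2 scale (SE 0.29, edgeR adjusted p = 0.0334) and HIST1H2AC from 71.6 ± 5.13 to 23.7 ± 7.82 CPM (log2 fold change −1.60, SE 0.22, edgeR adjusted p = 0.041). HIST2H2BE lay at −1.40 and HIST1H2BG at −1.66, with adjusted p = 0.0511 and 0.0832 by edgeR. The list median was −1.31, −1.32 and −1.47 in KD1, KD2 and KD3. There the list written to mark RNA quality, with 8 of 8 members negative, had medians of −0.74, −0.62 and −0.05 against −0.53 to 0.46 in the controls (camera adjusted p = 0.0652). For the histone list camera gave an adjusted p = 5.40e-08 with the preset and an adjusted p = 0.0594 with an estimated correlation.

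Genes of the interferon response were lower as a list (camera adjusted p = 2.77e-10, and adjusted p = 0.428 with an estimated correlation). Of 27 tested members 23 had a negative log2 fold change, 3 fell over all genes tested and 16 when adjusted over the list alone. IFI27 fell from 77.7 ± 6.61 to 28 ± 1.93 CPM (log2 fold change −1.47, SE 0.13, edgeR adjusted p = 0.0164). RSAD2, an antiviral enzyme, and BST2, which tethers virus particles, fell by 2.10 and 1.46 on the log2 scale. ISG15, a ubiquitin-like protein, lay at −2.01 (edgeR adjusted p = 0.0512). The list median was −0.48, −0.61 and −1.12 in KD1, KD2 and KD3.

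Genes of the unfolded protein response were lower as well (camera adjusted p = 1.36e-09, and adjusted p = 0.48 with an estimated correlation). Of 21 tested members 20 had a negative log2 fold change, 1 fell over all genes tested and 14 when adjusted over the list alone. PDIA4, a disulfide isomerase of the endoplasmic reticulum, fell from 1390 ± 209 to 387 ± 141 CPM (log2 fold change −1.84, SE 0.26, edgeR adjusted p = 0.045). PDIA5, an isomerase outside the list, fell from 53.5 ± 1.27 to 29.9 ± 0.399 CPM (−0.84, SE 0.12, edgeR adjusted p = 0.0421). CRELD2 lay at −1.27 and HYOU1, a chaperone, at −1.46, with adjusted p = 0.0511 and 0.0941 by edgeR. The list median was −1.56 in KD1, −1.54 in KD2 and −0.43 in KD3, and the median fold change moved from −1.01 to −1.58 without KD3.

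The libraries labelled HHEX shRNA did not form a single group. KD1 and KD2 correlated at r = 0.989 over the log2 CPM of the tested genes, and with KD3 at 0.955 and 0.956. KD3 correlated with the controls at 0.971 to 0.977, and the controls with each other at 0.982 to 0.985. The correlations are across genes, which are not independent replicates. KD1 and KD2 differed by more than sampling noise, with a mean chi-square of 7.125 per gene where equal libraries give 1, and were kept as separate samples. They were the closest pair, with 10.83 to 16.79 between controls, and the value does not show that they came from separate cultures, so that p-values measure the spread between these libraries, part of which may be technical. On the first principal component, with 56.2% of the variance, KD1 and KD2 stood at −52.9 and −53.4, KD3 at 21.9 and the controls at 22.8 to 33.3. On the next, with 18.4%, KD3 stood at −44.9. Genes more than 2-fold from the control mean numbered 1775 in KD1, 1818 in KD2 and 793 in KD3, against 437 to 441 in the control libraries, each set against the mean of the other 2.

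**Figure D3:**
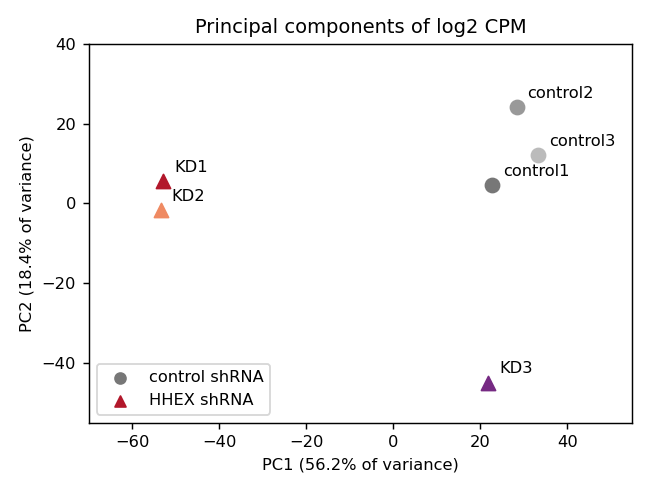
The first and second principal components of log2 CPM, with 56.2% and 18.4% of the variance, for the 3 control libraries (circles) and the 3 libraries labelled HHEX shRNA (triangles). KD1 and KD2 lie together at −52.9 and −53.4 on the first, and KD3 lies at 21.9, next to the controls, and apart from them on the second at −44.9.

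Proliferation genes followed that division. The mitosis list was higher (28 of 28 tested members with a positive log2 fold change, camera adjusted p = 0.000473, and adjusted p = 0.59 with an estimated correlation), with medians of 1.25 in KD1, 1.25 in KD2 and −0.60 in KD3. MKI67, a marker of cycling cells, was at 123 ± 30.5 CPM in the controls and at 401, 469 and 73.4 CPM in KD1, KD2 and KD3. The DNA replication list was higher too (27 of 28 members, camera adjusted p = 3.16e-05, and adjusted p = 0.559 with an estimated correlation), with medians of 0.99, 0.92 and −0.29. CCNE2, a cyclin of S phase entry, lay at 35.6, 35.3 and 12.5 CPM against 10.4 ± 1.6 CPM in the controls. Of either list 0 members passed edgeR's test over all genes or over the list alone. Without KD3 the medians were 1.27 for mitosis and 0.97 for DNA replication, in place of 0.84 and 0.63.

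Genes of the amino acid response driven by ATF4 were lower as a list (camera adjusted p = 0.00272, and adjusted p = 0.559 with an estimated correlation), and 0 of 25 members passed edgeR's test on their own, over all genes or over the list alone. The list median was −1.87 in KD1, −1.90 in KD2 and 0.14 in KD3. WARS, a tRNA synthetase, was at 544 ± 68.3 CPM in the controls and at 126, 114 and 448 CPM in KD1, KD2 and KD3. SHMT2, an enzyme of serine metabolism, was at 328 ± 19 CPM and at 153, 131 and 326 CPM. The median fold change of −0.87 became −0.54 without KD1, −0.51 without KD2 and −1.86 without KD3. In the other direction, the NRF2 list of oxidative stress genes (5 of 18 members higher over the list alone, camera adjusted p = 0.000327, and adjusted p = 0.559 with an estimated correlation) had medians of 0.13, 0.07 and 1.31, against −0.11 to 0.16 in the controls. GCLM, a subunit of the enzyme that starts glutathione synthesis, was at 16 ± 2.29 CPM in the controls and at 52.3, 53.2 and 148 CPM. ABCC2, an exporter of conjugates, was at 2.64 ± 0.474 and at 6.68, 6.37 and 6.57 CPM (edgeR adjusted p = 0.0794). The immediate early list (0 of 18 members past edgeR's test over all genes or over the list alone, camera adjusted p = 0.0392, and adjusted p = 0.59 with an estimated correlation) had medians of 0.16, 0 and 0.86, against −0.19 to 0.42 in the controls. Without KD3 the NRF2 median fell to 0.13 and that of the immediate early genes to 0.13, neither list passed (camera adjusted p = 0.222 and 0.981), and the camera direction of the immediate early list turned to lower. Without control3 the immediate early list did not pass either (0.0535).

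Several signalling lists were higher with smaller medians. In KD1, KD2 and KD3 the list medians were 0.37, 0.41 and 0.06 for MAPK output, whose control libraries spanned −0.17 to 0.10, 0.49, 0.57 and 0.18 for TGF-beta targets, 0.38, 0.36 and 0.24 for YAP and TAZ targets, and 0.30, 0.24 and 0.60 for NF-kB cytokines. MAPK output (median log2 fold change 0.40, camera adjusted p = 0.00156, and adjusted p = 0.48 with an estimated correlation) had 4 of 22 members higher over the list alone, among them FOSL1, a subunit of AP-1, at 153 ± 25.2 against 363 ± 74.1 CPM, and LIF, a cytokine, at 4.9 ± 0.89 against 10.4 ± 0.336 CPM. TGF-beta targets (0.39, camera adjusted p = 0.00156, and adjusted p = 0.428 with an estimated correlation) had 5 of 21. YAP and TAZ targets (0.30, camera adjusted p = 0.00562, and adjusted p = 0.48 with an estimated correlation) had 9 of 20 higher and 1 lower, with CYR61 at 420 ± 39.2 against 624 ± 68.3 CPM. NF-kB cytokines (0.35, camera adjusted p = 0.000327, and adjusted p = 0.399 with an estimated correlation) had 6 of 21, and CXCL8 over all genes tested. PTGS2, an enzyme of prostaglandin synthesis, was at 18.3 ± 3.22 CPM in the controls and at 54.5, 55.5 and 29.2 CPM in KD1, KD2 and KD3. Without KD3 the cytokine list did not pass (median 0.23, camera adjusted p = 0.103).

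Among metabolic lists, hypoxia and glycolysis genes were higher (median log2 fold change 0.43, 6 of 26 members over the list alone, camera adjusted p = 0.000327, and adjusted p = 0.559 with an estimated correlation). LDHA, lactate dehydrogenase, was at 1430 ± 289 CPM in the controls and at 4010, 3810 and 1890 CPM in KD1, KD2 and KD3. The list medians were 0.47, 0.39 and 0.38 in these libraries and 0.27, 0.27 and −0.50 in control1, control2 and control3, so that control3 stood apart. Without control3 the median fold change was 0.20 (camera adjusted p = 0.0206). Cholesterol synthesis genes, with medians of 0.40, 0.35 and −0.09 in KD1, KD2 and KD3, were higher as a list (0.36, 3 of 24 members higher and 1 lower over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.559 with an estimated correlation), but not without KD1 or control3 (0.0844 and 0.0811). Fatty acid synthesis genes (0.24, camera adjusted p = 0.0254, and adjusted p = 0.559 with an estimated correlation) had 3 of 15 members higher over the list alone, among them ELOVL6, an elongase, at 19.6 ± 1.96 against 36 ± 1.89 CPM, and 1 lower, SREBF1. That list did not pass without control2 or control3 (0.0586 and 0.119). Mitochondrial DNA genes, with medians of 0.51, 0.60 and −0.06 against −0.21 to 0.22 in the controls, were higher as a list (0.38, camera adjusted p = 0.0199, and adjusted p = 0.59 with an estimated correlation), but did not pass without KD1, KD2 or control3 (0.0962, 0.0776 and 0.107). The median was 0.23, 0.27 and 0.31 without these, and 0.57 without KD3. Nuclear genes of oxidative phosphorylation, with medians of 0.28, 0.15 and −0.03, were higher as a list (0.09, camera adjusted p = 0.0422, and adjusted p = 0.691 with an estimated correlation), but did not pass without KD1, KD2, control1 or control3 (0.401, 0.051, 0.197 and 0.292), nor with upper-quartile factors (0.0595), and their median was 0.05 without KD1, 0.21 without KD3 and 0.20 without control2. For this list the controls had medians of −0.12, 0.30 and −0.18, so that all 3 libraries labelled HHEX shRNA lay within the control range. Nucleolar MYC targets were higher (0.15, camera adjusted p = 0.0125, and adjusted p = 0.428 with an estimated correlation), with NOP58 at 147 ± 3.43 against 208 ± 16.6 CPM. Cytosolic ribosomal protein genes were lower (−0.18, 34 of 34 members negative, camera adjusted p = 0.0146, and adjusted p = 0.692 with an estimated correlation), with medians of −0.31, −0.50 and 0.20 in KD1, KD2 and KD3 and of −0.20 to 0.25 in the controls. Their median fold change was −0.38 without KD3 (adjusted p = 2.2e-05), −0.11 without KD1, −0.03 without KD2 and −0.07 without control2, and they did not pass without the last 3 (0.0962, 0.612 and 0.266), nor after correction for GC content and transcript length (0.183). Of these mitochondrial, MYC and ribosomal lists 0 members passed edgeR's test over the list alone.

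**Figure D4:**
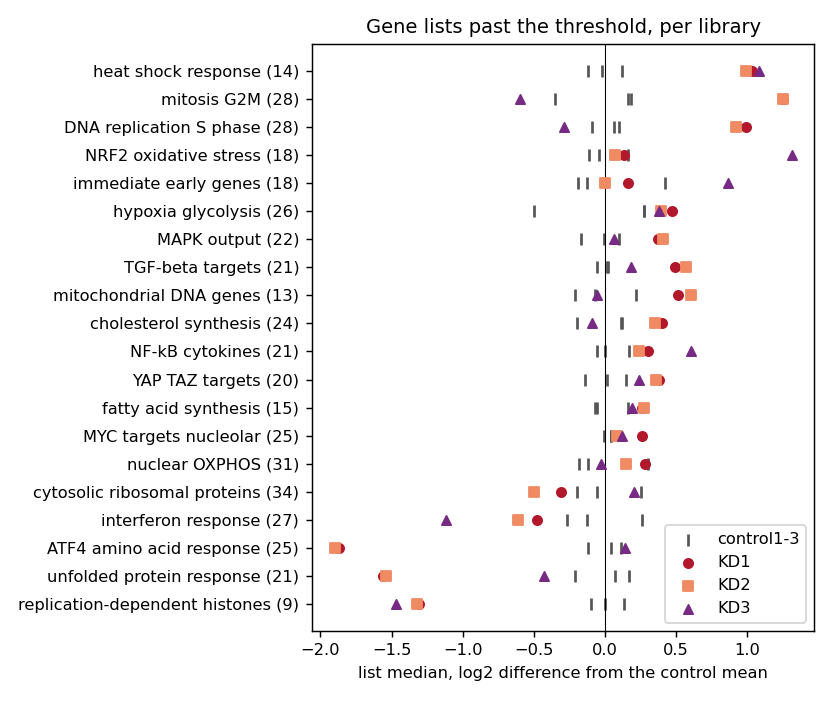
The 20 lists past the threshold (vertical axis, tested members in parentheses), with the list median of each library as log2 difference from the control mean (horizontal axis). Circles, squares and triangles are the libraries labelled KD1, KD2 and KD3, and grey ticks the 3 control libraries, each set against the mean of the other controls. Heat shock lies at 1.03, 0.99 and 1.08 and histones at −1.31, −1.32 and −1.47, while mitosis lies at 1.25, 1.25 and −0.60.

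In all, 20 of 31 tested lists passed camera with the preset correlation, 15 higher and 5 lower, and 0 with an estimated one, where 3 had an unadjusted p under 0.05. The estimated form has few degrees of freedom here, so its 0 calls do not show that correlation between genes made the others. The 9 other splits of the 6 libraries into 3 and 3, which each set a control beside KD1 or KD2, gave 6 to 15 lists with the preset correlation. The fry test, of whether a list's genes move on balance one way, called 2, heat shock and histones (adjusted p = 0.00179 and 0.000889), and 12 for change in either direction. These 12 include 4 lists that did not pass camera, thyroid differentiation (adjusted p = 0.0452), integrins (0.000228), angiogenic factors (0.00187) and Notch targets (0.0198).

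Thyroid differentiation genes did not pass camera (median 0.03 over 9 tested members, adjusted p = 0.669), with GLIS3 at 3.58 ± 0.311 against 5.82 ± 0.987 CPM. Nor did Wnt targets (0.11, adjusted p = 0.566), although CD44, a receptor of hyaluronan, was higher over the list alone at 529 ± 56.4 against 895 ± 184 CPM and PRICKLE1 lower at 4.19 ± 0.855 against 1.26 ± 0.561 CPM. Of the TLE co-repressors 4 were tested, 0 passed edgeR's test over all genes and 1, TLE3, when adjusted over the list alone. TLE3 was at 1.36 ± 0.378 against 4.42 ± 1.34 CPM (log2 fold change 1.70, SE 0.37, edgeR adjusted p = 0.0986), and TLE1 at 36.1 ± 2.68 against 46.8 ± 6.45 CPM. TLE4 was at 72.6 ± 9.4 CPM in the controls and at 181, 210 and 48.7 CPM in KD1, KD2 and KD3, and AES, also called TLE5, at 37 ± 15.6 against 28.3 ± 3.02 CPM. Epithelial genes (−0.38) and mesenchymal genes (0.18) each had an adjusted p = 0.0587 by camera. Of the epithelial genes 11 of 14 were negative, with CLDN4 at 8.39 ± 1.07 against 5.05 ± 1.94 CPM, and KRT7 went against the list at 407 ± 34.5 against 621 ± 139 CPM. SNAI2, a mesenchymal gene, lay at 3.8 ± 0.727 against 7.77 ± 1.35 CPM. Both lists passed without KD3 (medians −0.82 and 0.22, adjusted p = 0.0132 and 0.0349), and the epithelial genes also without control3 (−0.52, adjusted p = 0.0146). Collagen and matrix genes (−0.05, adjusted p = 0.225), integrins (−0.11, adjusted p = 0.566), Notch targets (0.07, adjusted p = 0.749), angiogenic factors (0.16, adjusted p = 0.39), p53 targets (0.01, camera direction lower, adjusted p = 0.922) and apoptosis genes (0.07, adjusted p = 0.318) did not pass. With 1 library left out, the angiogenic median ran from 0.12 to 0.43 and the Notch median from −0.03 to 0.4, and neither list passed. Adjusted over the list alone, 3 integrins and 2 matrix genes were lower, 2 angiogenic factors were higher and 2 lower, 3 apoptosis genes were higher and 2 lower, and 1 Notch target was higher. Over all genes PGF alone among them passed. Other members with small p were LAMA5, a laminin chain, at 1120 ± 121 against 477 ± 87.5 CPM (edgeR adjusted p = 0.0511), and ITGB4, an integrin of hemidesmosomes, at 278 ± 42.7 against 151 ± 3.97 CPM (edgeR adjusted p = 0.0584).

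The transcripts of the list written to mark RNA quality had a median of −0.47 (camera adjusted p = 0.0652), with library medians of −0.74 in KD1, −0.62 in KD2 and −0.05 in KD3 and of −0.53 to 0.46 in the controls. They passed without KD3 or control1 (medians −0.69 and −0.48, camera adjusted p = 0.0297 and 0.0206). Without KD1, KD2, control2 or control3 they did not pass (medians −0.29, −0.31, −0.49 and −0.41, camera adjusted p = 0.241, 0.0715, 0.0549 and 0.298). NEAT1 was at 900 ± 305 against 464 ± 38.1 CPM. SNHG1 was at 259 ± 42.4 CPM in the controls and at 92.9, 90.9 and 313 CPM in KD1, KD2 and KD3. SNHG5 was at 42 ± 8.45 CPM and at 17.3, 18.2 and 41.6 CPM. Whether the members of this list measure RNA quality in these libraries was not tested. Markers of other cell types had too few tested members for a list test: 3 of fibroblasts, 2 of leukocytes, 4 of endothelium and 3 of neural cells. COL3A1, the most abundant of the fibroblast markers, was at 45.9 ± 8.18 CPM in the controls and at 36.5, 40.9 and 9.96 CPM in KD1, KD2 and KD3. The fibroblast markers had medians of 0.11, −0.15 and −0.30 in these libraries and the leukocyte markers of 0.08, −0.54 and 0.13, with CD14 at 3.71 ± 0.977 against 3.36 ± 1.11 CPM. All 4 endothelial markers had a negative log2 fold change, with medians of −0.34, −0.49 and −1.10. TIE1 was lower over the list alone, at 16.1 ± 3.65 against 8.14 ± 2.15 CPM, EGFL7 lay at 34.9 ± 13.1 against 21.7 ± 4.08 CPM, and CDH5 at 10.6 ± 0.297 CPM in the controls and 11, 9.95 and 2.61 CPM in KD1, KD2 and KD3. All 3 neural markers were negative, with medians of −0.40, −1.58 and 0.30. MAP2 was at 6.51 ± 0.986 CPM and at 1.49, 2.08 and 7.55 CPM, and MBP at 32.9 ± 3.27 CPM and at 24.8, 25 and 41.9 CPM.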

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

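The 26 changed genes kept their direction in each alternative. Their direction could hardly turn, since their groups did not overlap and their log2 fold changes were at least 0.84 in size. Counts of calls moved. With edgeR, RLE factors gave 31 changed genes, upper-quartile factors 35 (15 higher and 20 lower), library size alone 37 (15 higher and 22 lower), and at least 10 counts in at least 3 libraries 39 (20 higher and 19 lower). Upper-quartile factors and library size alone moved the higher share from 57.7% to 42.9% and 40.5%, and no scaling moved the median of all genes by over 0.1. All 26 genes were called in each of these settings. DESeq2 called 774 genes (437 higher, 337 lower), limma-voom 28, and edgeR with no filter on low counts 1359 (724 higher, 635 lower), and the cause was not tested. Against a fold of 1.5, glmTreat of edgeR called 0 genes, with 0 higher and 0 lower, where 664 had an unadjusted p under 0.05. Of the alternatives chosen after the data were seen, unnamed loci gave 31 genes, the correction for GC content and length 34, and voom with library weights 5100 (2450 higher, 2650 lower), the last with a weight of 0.196 for KD3. Leaving out 1 library at a time gave 0 to 4675 changed genes, 0 to 2438 higher and 0 to 2237 lower. The highest count came without KD3 (6233 at an unadjusted p under 0.05), without KD1, KD2, control2 or control3 there were 0 calls by edgeR (1789, 1625, 1947 and 1806 at an unadjusted p under 0.05; no other tool was run on these sets), and without control1 there was 1, ISG15. HHEX stayed below 0 and past no threshold in each alternative, from −0.73 without KD1 to −0.11 without KD3. Of the 20 lists, 12 passed camera in all 15 alternative settings of scaling, filter, correction and libraries, and 8 did not. With library weights, the immediate early, NF-kB and NRF2 lists no longer passed (adjusted p = 0.646, 0.0624 and 0.11), while epithelial, mesenchymal and RNA quality genes did (0.0362, 0.0262 and 0.0109), and limma-voom without weights brought epithelial and RNA quality genes past the threshold (0.0488 and 0.0365), as did the GC and length correction for the latter (0.0385). An estimated correlation left 0 lists and fry 2. Immediate early genes turned to the lower side by camera without KD3, with a median from 0.13 to 0.81 over the left-out libraries (camera adjusted p from 0.000397 to 0.981). No paired analysis was possible because the columns carry no replicate label, so the planned replicate block, the block on the first number and the sum of the libraries that share it were not run. The planned pseudocounts and filters for normalized values did not apply to counts. At this depth and spread, 41% of simulated 2-fold changes were recovered, so that genes without a call are not shown to be unchanged.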

Other observations

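The tests of the splits, of a swap, of a wrong label, of the HHEX level and of S phase, and the genes named here for single libraries, were chosen after the data were seen; the tests of depth, of GC content and length, and of RNA without a poly(A) tail were fixed before their results. Among the genes farthest from the control mean in the libraries labelled KD1 and KD2 were several that lay nearer to it in KD3. DDIT3, a transcription factor induced by stress of the endoplasmic reticulum, was at 62.7 ± 16.5 CPM in the controls (SD, n = 3) and at 2.09, 1.57 and 53.9 CPM in KD1, KD2 and KD3. GDF15, a stress-induced cytokine, was at 27.6 ± 8.41 CPM and at 0.473, 0.572 and 45.3 CPM. HERPUD1, of protein degradation at the endoplasmic reticulum, was at 460 ± 93.3 CPM and at 43.1, 47.2 and 377 CPM, and HSPA5, its main chaperone, at 15200 ± 2980 CPM and at 1640, 1530 and 9010 CPM. TSLP, a cytokine, was at 38.4 ± 8.24 CPM and at 3.51, 5.37 and 50.2 CPM. On the higher side, RGS4, a regulator of G protein signalling, was at 43.8 ± 10.8 CPM and at 413, 391 and 34.2 CPM, and CYP24A1, which degrades vitamin D, at 84.5 ± 5.54 CPM and at 518, 553 and 69.1 CPM. None of these genes passed the group test.

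Among the genes farthest from the control mean in KD3, some lay nearer to it in KD1 and KD2 and others did not. HMOX1, heme oxygenase, was at 6.63 ± 1.35 CPM in the controls and at 7.09, 4.15 and 570 CPM in KD1, KD2 and KD3. HSPA6, a heat-inducible chaperone, was at 2.87 ± 1.43 CPM and at 5.54, 5.08 and 223 CPM, and DNAJB1 at 178 ± 27.7 CPM and at 242, 232 and 1200 CPM. FOS was at 4.9 ± 1.28 CPM and at 6.95, 5.94 and 176 CPM, and EGR1 at 38 ± 4.1 CPM and at 17.6, 19.3 and 357 CPM. F2RL3, a thrombin receptor, was lower in all 3, at 20.4 ± 1.29 CPM in the controls and at 0.675, 0.429 and 4.94 CPM. KRT17 and ISG15 stood at nearly equal levels in the 3 libraries, at 8.85, 9.87 and 10.3 CPM and at 21.4, 20.9 and 22.2 CPM, against 33 ± 5.37 and 86.4 ± 36.1 CPM.

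KD3 lay nearer to the controls than to KD1 and KD2. Its distance to the mean of KD1 and KD2 was 1.48 times its distance to the control mean. The ratio was 1.47 (bootstrap SD 0.02) with every library thinned to the smallest total. Totals ran only from 13333245 to 15144176 counts, with KD3 between KD1 and KD2. Thinning could thus hardly move the ratio and does not decide on depth. After correction for GC content and transcript length the ratio was 1.52 (SD 0.021), which argues against these biases. The bootstrap drew genes, here and below, so that its SD does not cover the spread between libraries. A swap between the groups would leave a control near KD1 and KD2, but the lowest correlation between controls exceeded the highest of a control with either by 0.02, and it exceeded the highest of KD3 with a control by 0.0048, where the correlations between controls had an SD of 0.0014, which argues against KD3 being a further control of their batch. HHEX in KD3, at 7.13 CPM against 12.5 ± 0.439 CPM in the controls, runs with its label. The heat shock (1.08) and histone (−1.47) medians of KD3 lay near those of KD1 and KD2. These lists stood out in a comparison that includes KD3, so they are no separate evidence for its label. A control from another batch or culture state, a difference in culture between the libraries labelled HHEX shRNA, and a different hairpin or response stay open, since the columns carry no replicate label.

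HHEX was not lower in the library labelled KD1 than in the controls. Its lower Poisson bound there exceeded the higher of the upper bounds in KD2 and KD3 by 3.34 CPM, which counting error does not give. The lowest correlation between controls exceeded the highest of KD1 with a control by 0.0212 (SD between controls 0.0014), which argues against KD1 being a control of their batch. Its correlation of 0.989 with KD2 runs with its label. The heat shock (1.03) and histone (−1.31) medians of KD1 lay near those of KD2 and KD3. These lists stood out in a comparison that includes KD1, so they are no separate evidence for its label. A control from another batch shared with KD2 stays open, as do cells given the hairpin in which HHEX was not reduced when RNA was taken and hairpin effects that do not follow HHEX.

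Of 24 tested replication-dependent histone genes, which include the 9 of the list, 23 had a negative log2 fold change (median −1.40), and of the 15 outside the list 14, with 0 called by edgeR over all genes (10 at an unadjusted p under 0.05) and medians of −1.01, −1.15 and −0.85 in KD1, KD2 and KD3 against −0.35 to 0.15 in the controls. The median of the 12 tested small non-coding RNA genes, which in the main lack a poly(A) tail, lay 1.18 above that of the 24 (bootstrap SD of the difference 0.34). The libraries were made by mRNA capture, and reads of host genes of small nucleolar RNAs were not separated. The difference thus does not decide on a lower yield of RNA without a poly(A) tail. The RNA quality list lay lower in KD1 and KD2 (−0.74 and −0.62), though not in KD3 (−0.05), against −0.53 to 0.46 in the controls. After correction for GC content and transcript length the histone median was −1.20 (SD 0.23), which argues against these biases as the whole cause. In KD1 and KD2 the DNA replication list lay above the highest control by at least 0.82 on the log2 scale, which argues against fewer cells in S phase. The medians of the 24 histone genes there were −1.21 and −1.26. In KD3 the DNA replication list lay at −0.20 from the lowest control but 0.85 above the histone median there (bootstrap SD 0.16). The sign of that list goes with fewer such cells and its size falls short, so this stays open in KD3. How closely the captured histone transcripts follow S phase was not measured. Several of these transcripts can carry a poly(A) tail, and a change in that processing is a possible explanation that was not tested.

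For the count of changed genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 26 genes and was the only 1 with as many, and the highest other gave 0 by edgeR. Each other split sets a control beside KD1 or KD2, so the large difference between these libraries enters the spread within groups. Few calls there were thus close to given in advance, and these splits are no null for the 26 genes. For lists the real split gave 20, again the only 1 with as many, and the others 6 to 15, the highest in the split of KD1, KD2 and control1 against KD3, control2 and control3. The other splits can carry the difference of KD1 and KD2 from the controls, so they are no null for the lists either.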
